A study of Mus musculus with 6 samples.

How the data were processed

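RNA was measured in cells from mouse hearts on the C57BL/6 background. Per the labels, each library came from a pool of 5 or 6 hearts that were digested with collagenase and hyaluronidase. Non-myocyte cells were freed of debris and enriched with magnetic beads against Cd11b, the surface integrin encoded by Itgam that marks myeloid cells. Bead enrichment leaves an unknown share of other heart cells, and no purity value is given in the sources used here. RNA was extracted with the RNeasy Mini kit and made into libraries with the NEBNext Ultra II Directional kit, per the labels' protocols. There were 3 pools of floxed Egfr controls without deletion (WT) and 3 pools with Egfr deleted in myeloid cells (KO). The pool was the replicate, so p-values measure the spread between pools and not between single animals.

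The deposited values are whole-number counts of reads per Ensembl gene in each library, with no normalization by the authors. STAR, HTSeq and DESeq2 and the mouse build GRCm38 are named in the submitters' processing notes. Their versions, the annotation release and the strand setting are not given in the sources used here. Each table also holds 5 counters that name no gene. Reads outside annotated genes made up 5.90% to 8.62% of all counted reads, reads overlapping several genes 1.49% to 1.72%, and reads aligned to several places 7.58% to 8.67%. The other two counters were at 0 in every library. All 5 were left out of library sizes and tests. Because reads that fit several places were not assigned to genes, near-identical gene copies can be undercounted, and levels of immunoglobulin segments and of the lysozyme pair Lyz1 and Lyz2 are uncertain to that extent.

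Of 55487 gene identifiers, 55141 had a symbol in the gene name table used here, and 346 had none. In the GENCODE M21 annotation of GRCm38, 55227 were present. Coordinates are from GENCODE M21, which corresponds to Ensembl release 96. Gene totals ranged from 17780707 to 27485129 reads per library. At this depth Egfr was counted 406 to 1421 times per library. Pairs of libraries of the same group differed by far more than counting noise, with a chi-square per degree of freedom of 37.9 to 83.9, and all 6 were kept as separate samples.

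Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10), which left 15707. Library sizes were scaled by TMM, and the quasi-likelihood F test (glmQLFit with its default settings, glmQLFTest) compared KO with WT with no other term. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The common biological coefficient of variation was 0.239. Levels are TMM-scaled counts relative to library size (CPM), given as mean ± SD over 3 pools. Log2 fold changes are KO against WT with a standard error (SE) computed as the size of the change over the square root of its F value. For single values, an exact permutation test of 3 against 3 pools cannot give a two-sided p below 0.1.

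The design, the gene lists, the rule for named genes and the first set of other settings were chosen before the data were examined. The rule named Egfr, Lyz2 and Itgam. It then took the genes past the threshold with the largest changes, at a mean CPM of at least 1 and with no overlap between groups. Since fewer than 20 genes passed, genes with the smallest p-values filled the number up to 20. Within a list, up to 4 members with the smallest p-values and a mean CPM of at least 1 are named. Predicted genes without a given name were passed over, and a few list members that the rule would name are not reported here.

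There were 37 gene lists, of cell type markers and pathways, of which 35 had at least 5 tested members. The sex-linked and adipocyte lists had too few. Lists were tested with camera (limma 3.58.1, two-sided) at the preset inter-gene correlation of 0.01, adjusted over the 35 lists. A list's members were also adjusted over the list alone. The first set of other settings comprised DESeq2 1.42.0, limma-voom, other scalings, no filter and a stricter one (mean CPM of at least 5), a 1.2-fold minimum change, the replicate number as a block, each library left out in turn, and, for lists, an estimated correlation and fry, a rotation test.

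Settings added after seeing the data were a covariate for Y-linked expression, a covariate for the mean level of the vessel wall and fibroblast lists, and bias-adjusted deviances in edgeR. A check of transcript length and GC content used Biostrings 2.70.1. Figures were drawn with matplotlib 3.10.9. The procedure was tested on simulated counts for KO against WT over 15707 genes. It recovered 55 of 100 genes changed 2-fold and 87 of 100 changed 4-fold, with 0 of the wrong sign, and called 10 unchanged genes. Besides the 1 list that was shifted, camera at the preset correlation called 3 other lists, which could hold changed genes. Which Egfr exons were removed was not analysed here, because the tables hold 1 count per gene.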

Results

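The series measured gene expression in Cd11b-enriched non-myocyte cells of the mouse heart, a preparation enriched for macrophages and other myeloid cells. It addressed how deletion of the epidermal growth factor receptor gene Egfr in myeloid cells alters expression in that preparation. Each of 6 libraries came from 1 pool of hearts, with 3 WT pools carrying floxed Egfr and 3 KO pools. The WT libraries held 27104205, 17780707 and 21356194 reads in genes, and the KO libraries held 27485129, 25199667 and 25961210.

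Egfr, the targeted receptor tyrosine kinase, fell to 36.4% of its WT level in the KO pools. Its level was 47.5 ± 6.29 CPM in WT and 17.3 ± 1.29 CPM in KO (SD, n = 3 each), and every KO pool lay below every WT pool. The log2 fold change was -1.46 (SE 0.13, edgeR adjusted p = 0.0449). Egfr (ENSMUSG00000020122) lies on chromosome 11 at 16752203 to 16918158 of GRCm38, on the plus strand. A gene count sums all exons, so transcripts that lack a deleted part still count. The direction held in all 6 fits that left out 1 library. The call was lost without WT replicate 2, WT replicate 3, KO replicate 1, KO replicate 2 or KO replicate 3, with edgeR adjusted p-values of 0.113 to 0.353, and it held without WT replicate 1 (adjusted p = 0.0119). The call was also lost with limma-voom (adjusted p = 0.0534) and with the replicate number as a block (edgeR adjusted p = 0.0501). In a fit added later, the level of vessel wall and fibroblast markers as a covariate ended it too (edgeR adjusted p = 0.351).

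Lyz2, which encodes the lysozyme of macrophages and neutrophils, fell from 5034 ± 1449 CPM in WT to 18.6 ± 1.06 CPM in KO (SD, n = 3 each). This was a 270-fold lower mean level, a log2 fold change of -8.08 (SE 0.33, edgeR adjusted p = 0.000178). Lyz2 (ENSMUSG00000069516) lies on chromosome 10 at 117277331 to 117282321, minus strand. Its neighbour Lyz1 (ENSMUSG00000069515), a closely related lysozyme gene at 117287797 to 117292868 on the same strand, was at 158 ± 80.6 CPM in WT and 976 ± 185 CPM in KO. The Lyz1 log2 fold change of 2.63 (SE 0.35) did not pass the test (edgeR adjusted p = 0.108). Itgam, which encodes Cd11b itself, was at 104 ± 31.6 CPM in WT and 149 ± 28.1 CPM in KO, with a log2 fold change of 0.51 (edgeR adjusted p = 0.341). Without WT replicate 1 Itgam passed, higher in KO with 0.79 (edgeR adjusted p = 0.0358).

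**Figure D1:**
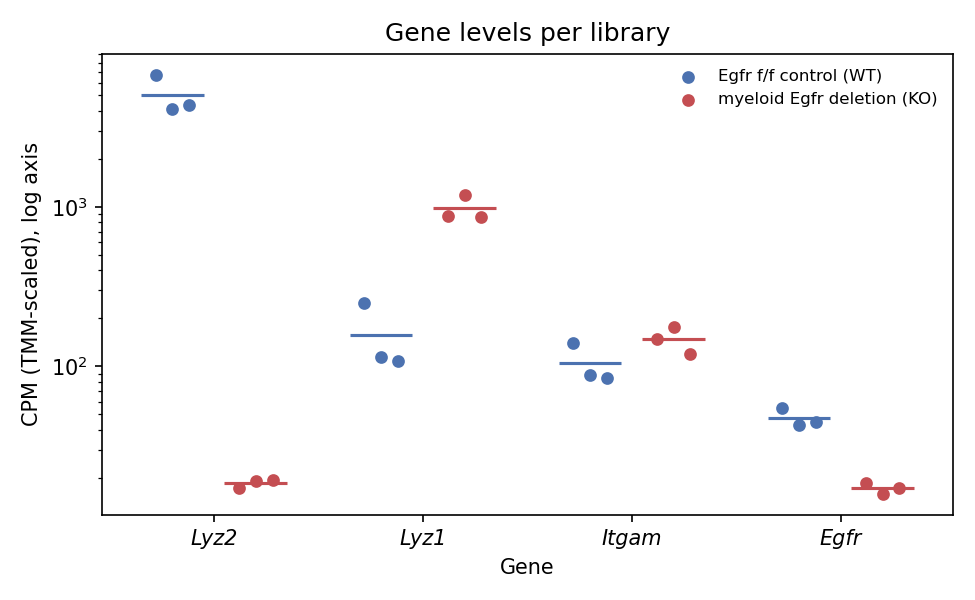
Levels of Lyz2, Lyz1, Itgam and Egfr in each library, in TMM-scaled CPM on a log axis, with points for the 3 WT (blue) and 3 KO (red) pools and a line at each group mean. Lyz2 lay between 17.4 and 19.3 CPM in the KO pools and between 4074 and 6700 CPM in the WT pools, and Egfr was lower in every KO pool than in every WT pool.

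Across all 15707 genes tested, only Lyz2 and Egfr passed the threshold in edgeR, with 0 genes higher and 2 lower in KO. At an unadjusted p under 0.05 there were 2409 genes, 749 higher and 1660 lower, where 785 would fall by chance on average. Because genes vary together, the number by chance can lie far from that average. The 9 other splits of the 6 libraries into 3 and 3 gave 197 to 1724 such genes. The split with 1724 joined WT replicate 1 with KO replicates 1 and 2, and so set both libraries with Y-linked expression on the same side. Unadjusted counts on leaving out 1 library ranged from 1353 (without WT replicate 3) to 3977 (without WT replicate 1), with 1404 without KO replicate 2. The KO and WT pools did not overlap for 19.7% of genes, against 10% by chance. This comprised 1507 genes with every KO pool above every WT pool and 1592 with every KO pool below. Without WT replicate 1 edgeR called 1338 genes, 376 higher and 962 lower. That pool differed less from the KO pools (chi-square per degree of freedom 41.3 to 58.5) than from the other WT pools (77.0 and 83.9). With all 6 libraries, DESeq2 called 831 genes, 170 higher and 661 lower, and edgeR without its expression filter called 782, 139 higher and 643 lower.

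The other genes named by the rule had edgeR adjusted p-values above 0.05 and are given as values. On the higher side, Saa3, an acute-phase serum amyloid, had the log2 fold change 2.83 (adjusted p = 0.0799), with 5.80 ± 1.46 CPM in WT and 41.4 ± 16.1 CPM in KO. H2-M2, a nonclassical MHC class I gene, had 2.61 and Serpina3f, a serine protease inhibitor, 1.92 (adjusted p = 0.0746 for both). Tagap1 (1.38), the coagulation factor gene F10 (1.46) and Wdfy1 (0.98) were also higher in every KO pool. So were the antibody genes Igha (3.41), Igkv3-10 (2.74), Igkv10-94 (2.19), Igkv5-39 (2.06), Igkv10-96 (1.65) and Iglv1 (1.55). Igha, the constant region of immunoglobulin A, was at 49.4 ± 34.7 CPM in WT and 525 ± 215 CPM in KO. On the lower side were Ptprg (-1.26, adjusted p = 0.0991), Adgrl4 (-1.20), Dach1 (-1.15), Cyyr1 (-1.12) and Rasgrf2 (-1.08). Adgrl4 is an adhesion receptor of endothelial cells. All 18 of these genes, Lyz1 included, passed the threshold under DESeq2, in edgeR without its expression filter, and without WT replicate 1. None of them passed with limma-voom or without WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 2, where only Lyz2 was called. With the replicate number as a block, only Igha of them passed (edgeR adjusted p = 0.0118).

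Lists of vessel wall and fibroblast markers had negative medians in KO and passed camera only at the preset correlation. All 21 endothelial genes tested had negative log2 fold changes, with a median of -1.00, and the receptors Kdr (-1.36, SE 0.24) and Flt1 (-1.12, SE 0.21), the phosphatase Ptprb (-1.08, SE 0.17) and Emcn (-1.18, SE 0.24) led the list. All 14 mural cell genes were negative too (median -0.81), led by the pericyte channel genes Abcc9 (-1.44, SE 0.23) and Kcnj8 (-1.22, SE 0.25), with Vtn (-1.16) and Cspg4 (-0.94). Among 20 fibroblast genes 19 were negative (median -1.09), with Col3a1 (-1.33, SE 0.42), Col6a1 (-1.21), Pdgfra (-1.13) and Pi16 (-1.12) first. None of these genes passed over all genes in edgeR with its filter and all 6 libraries, and 2 of the 55, Fabp4 and Cd36, also stand in another list. Of the 55, DESeq2 called 39 lower, edgeR without its filter 37 and edgeR without WT replicate 1 40, and none was called higher. Adjusted over the list alone, 19 endothelial, 12 mural and 17 fibroblast genes were lower and 0 higher. Camera placed all 3 lists below other genes at the preset correlation (adjusted p = 3.78e-24, 5.86e-14 and 1.96e-10), and none held with an estimated correlation (adjusted p = 0.52 with an estimated correlation for each). The KO pools lay below every WT pool in the mean endothelial and mural level, while the fibroblast level of WT replicate 1 lay among the KO pools. Without WT replicate 3 the fibroblast median was -0.63.

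**Figure D2:**
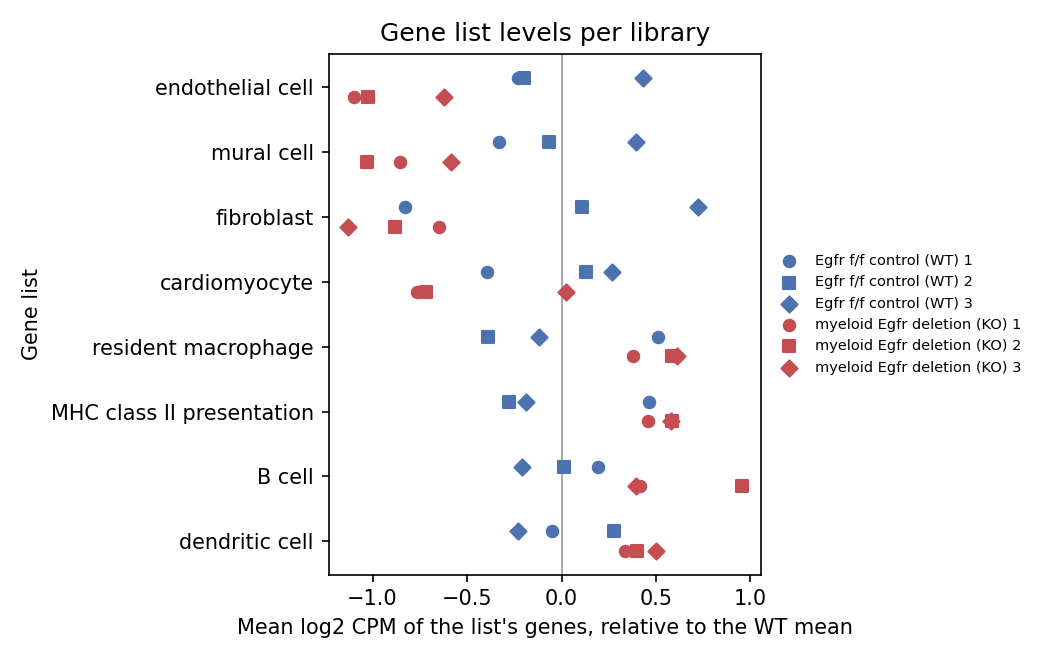
Mean log2 CPM of the genes of 8 lists in each library, relative to the mean of the 3 WT libraries (vertical line), with blue for WT, red for KO and a marker shape per replicate number. The endothelial level was -0.62 to -1.10 in KO and -0.23 to 0.43 in WT, and in the resident macrophage list WT replicate 1 (0.51) lay among the KO pools.

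Other non-myeloid lists also had lower medians in KO. The cardiomyocyte median was -0.50 over 20 genes, 19 of them negative, with Actc1 (-0.60), Myl2 (-0.53), Tpm1 (-0.54) and Ryr2 (-0.73). The mesothelial median was -0.68 over 10 genes, all negative, with Efemp1 (-0.92), Wt1 (-0.98), Lrrn4 (-0.82) and Upk3b (-0.67). For 9 Schwann cell genes the median was -0.76, with Cdh19 (-1.18), Gfra3 (-1.74) and S100b (-1.14). The erythroid median was -3.77 over 7 genes, with Alas2 (-4.16), Hbb-bt (-3.91) and Hba-a2 (-3.77). Blood-cell RNA in WT replicate 1 set that size: beta-globin Hbb-bs was at 1103 CPM there and at 45.9 and 85.8 CPM in the other WT pools, against 20.2 to 53.4 CPM in KO. Without WT replicate 1 the erythroid median was -1.01. No member of these 4 lists passed over all genes in edgeR with its filter and all 6 libraries, and adjusted over the list alone 0 cardiomyocyte, 1 mesothelial, 0 Schwann and 6 erythroid genes were lower. Over all genes, DESeq2 called 0, 1, 1 and 1 genes lower in that order. Without its filter edgeR called 0, 2, 1 and 6 lower, and without WT replicate 1 it called 1, 1, 1 and 0 lower. None was called higher. Camera called all 4 lists lower at the preset correlation (adjusted p = 3.15e-05, 0.00393, 0.01 and 0.00029). None held, with adjusted p = 0.614 with an estimated correlation for the cardiomyocyte list and adjusted p = 0.52 for the others. Leaving out WT replicate 2 ended the mesothelial call (median -0.44). Leaving out WT replicate 2 or KO replicate 3 ended the Schwann call (medians -0.84 and -0.81), and without KO replicate 1 the Schwann median was -1.31. The cardiomyocyte median was -0.77 without KO replicate 3.

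Lists of macrophages, antigen presentation and B cells had positive medians in KO and passed camera only at the preset correlation. In the resident macrophage, MHC class II and efferocytosis lists the level of WT replicate 1 lay among those of the KO pools. The heat shock level of KO replicate 2 (mean log2 CPM 8.19) lay below WT replicate 1 (8.24) and WT replicate 3 (8.48). For heat shock and efferocytosis levels the exact permutation p was 0.3. All 26 resident macrophage genes had positive log2 fold changes, with a median of 0.53. Among them were Timd4 (0.68, SE 0.23) and Folr2 (0.66, SE 0.24), markers of long-lived tissue macrophages, the Fc receptor Fcgr1 (0.59) and Ltc4s (0.72). All 14 genes of MHC class II presentation were positive as well (median 0.55), with the class II transactivator Ciita (0.77, SE 0.21), H2-Oa (0.74), H2-Ob (0.56) and H2-DMb2 (0.65). Of 15 B cell genes 14 were positive (median 0.63), with Igkc (1.09, SE 0.19), Blk (0.73) and Ighd (0.69). The dendritic cell median was 0.35 over 18 genes, with the migration receptor Ccr7 (0.97, SE 0.16), Clec9a (0.74), Ly6d (0.69) and Naaa (0.41). Heat shock genes had a median of 0.41 over 14 genes, with the chaperones Hsph1 (1.34, SE 0.36), Hspe1 (0.71), Hspd1 (0.65) and Dnaja1 (0.52). The efferocytosis median was 0.19 over 25 genes, of which 16 were positive, with the scavenger receptor Marco at 2.27 (SE 0.37), Timd4 and Fcgr1 as above, and Mfge8 at -0.61.

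No member of these 6 lists passed over all genes in edgeR with its filter and all 6 libraries. Without WT replicate 1 edgeR called 16 resident macrophage, 10 MHC class II, 9 efferocytosis, 5 dendritic cell, 4 B cell and 1 heat shock gene higher, and 1 B cell gene lower. DESeq2 called 5 B cell, 3 heat shock, 2 MHC class II, 1 dendritic cell, 1 efferocytosis and 0 resident macrophage genes higher, and 1 efferocytosis gene lower. Adjusted over the list alone, 0 resident macrophage, 3 MHC class II, 9 B cell, 1 dendritic cell, 3 heat shock and 1 efferocytosis gene were higher, and 1 B cell gene, Ebf1, was lower (-0.42). Camera called all 6 lists higher at the preset correlation, with adjusted p from 5.48e-10 (resident macrophage) to 0.01 (efferocytosis). None held: for efferocytosis the adjusted p = 0.614 with an estimated correlation, and for the others adjusted p = 0.52 with an estimated correlation. The resident macrophage and MHC class II medians were 0.80 and 0.84 without WT replicate 1, and 0.33 and 0.35 without WT replicate 2. Leaving out KO replicate 2 lowered the B cell median to 0.42, and leaving out WT replicate 2 ended the efferocytosis call (median 0.14).

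Genes close to the receptor were read from the list of EGFR family genes, and signalling from the MAPK feedback genes, which the pathway switches on. The EGFR family list includes Egfr itself, so its calls rest partly on the deleted gene, and no value without Egfr is given here. Vessel wall and fibroblast markers were lower in the same KO pools (median -1.00 over 55 genes), and these values were not resolved by cell type. The EGFR family median was -0.15 over 18 genes, with Egfr, Erbb2 (-0.88, SE 0.26), the ligand Ereg (-1.31, SE 0.42) and the adaptor Grb2 (0.38, SE 0.14). In edgeR with its filter and all 6 libraries, only Egfr of this list passed over all genes or adjusted over the list alone. DESeq2 called 2 genes of the list lower, and edgeR without WT replicate 1 called 4 lower and 1 higher. The MAPK feedback median was -0.29 over 15 genes, 11 of them negative. The signalling inhibitors Spry1 (-1.11, SE 0.28) and Spred2 (-0.44, SE 0.11) were lower adjusted over the list alone, and Spry4 (-1.01) and Spry2 (-0.65) were not. Over all genes, 0 members passed in edgeR with its filter and all 6 libraries, and 2 were lower in each of DESeq2, edgeR without its filter and edgeR without WT replicate 1. Neither list passed camera (adjusted p = 0.0664 for both, and adjusted p = 0.52 with an estimated correlation). At the preset correlation the EGFR family list passed as lower at a mean CPM of at least 5 and without WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 3 (camera adjusted p from 0.0135 to 0.0482). The MAPK feedback list passed as lower without WT replicate 2 or KO replicate 2 (camera adjusted p = 0.0196 and 0.0294) and with the replicate block (0.0417). Leaving out any 1 library nevertheless brought its median nearer to 0, to between -0.18 and -0.12. The immediate early median was -0.0027 over 26 genes (camera adjusted p = 0.831).

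Other immune cell lists did not pass in the genotype-only fit of all 6 libraries. The classical monocyte median was 0.24 while its mean was -0.26 and camera pointed down (adjusted p = 0.339). Lyz2 is a member, and F10 and Vcan (-1.16, SE 0.33) passed adjusted over the list alone. The nonclassical monocyte median was -0.02 (adjusted p = 0.781), with Fabp4 (-1.02) and Ace (-0.56) lower adjusted over the list alone. Both of these genes are also expressed in endothelial cells. The neutrophil median was 0.26 with a mean of -0.04 (adjusted p = 0.781), and its granule genes Ltf (-2.15), Camp (-2.35) and Ngp (-1.97) did not pass. The T cell median was -0.74, yet camera pointed up (adjusted p = 0.563), and the level was set by WT replicate 2, with Cd3e at 27.1 CPM there and at 0.85 and 1.12 CPM in the other WT pools. The NK cell median was -0.23 (adjusted p = 0.414), the mast cell median -0.56 (adjusted p = 0.101, Gata2 lower adjusted over the list alone) and the platelet median -0.56 (adjusted p = 0.0524). Leaving out 1 library gave calls for 5 of these lists at the preset correlation. Platelet genes passed as lower without WT replicate 3 (median -0.80) or KO replicate 2 (-0.74), and had -0.26 without WT replicate 1 and -0.38 without KO replicate 3. Mast cell genes passed as lower without WT replicate 2 (-0.74) and had -0.24 without WT replicate 3. T cell genes passed as higher without WT replicate 2 (2.29). Camera also called classical monocyte and neutrophil genes lower without WT replicate 3 (medians 0.15 and -0.0636) and without KO replicate 1 (0.0025 and -0.92).

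Inflammatory, metabolic and cell cycle lists did not pass in that fit with TMM scaling either. Medians were 0.12 for NF-kB cytokines and chemokines (Il12b 1.05, Nos2 -1.27, Cxcl1 -0.72), 0.16 for alternative activation (Trem2 0.50) and 0.02 for the interferon response (Mx1 0.57, Zbp1 0.51). They were 0.22 for myeloid adhesion and migration receptors, 0.14 for NADPH oxidase and antioxidant genes, 0.14 for cholesterol and lipid handling, 0.08 for oxidative phosphorylation, 0.06 for glycolysis and hypoxia and 0.10 for apoptosis. The mitochondrially encoded median was -0.13. Extracellular matrix remodelling had a median of 0.06, a mean of -0.09 and a camera direction of down, with Timp3 at -0.96 and Adamts1 at -1.04. Cell cycle genes had a median of -0.14 and a camera direction of up, and the immediate early list also had a negative median with camera pointing up. Among these lists the smallest camera adjusted p was 0.0664, and 0 members passed adjusted over the list alone. Without WT replicate 1, adhesion and migration receptors (median 0.43), alternative activation (0.42), NADPH oxidase (0.29) and cholesterol genes (0.24) passed as higher at the preset correlation. Without KO replicate 2, alternative activation (0.25), NF-kB (0.24), NADPH oxidase (0.22), cholesterol (0.16), glycolysis (0.12), oxidative phosphorylation (0.11) and interferon genes (0.10) did so. The cell cycle list passed as higher without WT replicate 2 (0.34), and oxidative phosphorylation without WT replicate 3 or KO replicate 1 (0.12 each). The oxidative phosphorylation median was 0.03 without WT replicate 2 and 0.0067 without KO replicate 3. Mitochondrially encoded genes passed as lower without WT replicate 3 (-0.28) or KO replicate 2 (-0.32). With library totals only, NADPH oxidase genes passed as higher (0.10).

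The sex-linked and adipocyte lists were too short to test. Xist, expressed from the inactive X chromosome, was at 0.27 and 0.15 CPM in WT replicate 1 and KO replicate 1, and at 344 to 602 CPM in the other 4 libraries. The Y-linked gene Eif2s3y was at 55.8 and 52.6 CPM in those 2 libraries and at most 0.52 CPM in the others. With 1 such pool in each group, the genotype comparison of all 6 libraries was balanced for this difference. Every fit that left out 1 library was unbalanced for it. This was strongest without WT replicate 1 or without KO replicate 1, where only 1 group held such a pool.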

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

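The share given here is a value, and no tests were run on it. Reads overlapping several genes, which take no part in the comparison, made up a mean of 1.69% of counted reads in KO (1.68%, 1.67% and 1.72%), above each of the WT libraries (1.63%, 1.49% and 1.56%).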

How the results depend on the processing

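The covariates and bias-adjusted deviances were tests chosen after the result was seen. Lyz2 passed in every setting run. The counts of 2 genes in all and 2 lower held with median-of-ratios, upper-quartile and library-total scaling, a mean CPM of at least 5 and bias-adjusted deviances alone. DESeq2 called 831 (170 higher, 661 lower), edgeR without a filter 782 (139, 643), limma-voom 1 (0, 1), a 1.2-fold minimum change 1, the Y-linked covariate 3 (0, 3) and the vessel wall and fibroblast covariate 1 (0, 1). Leaving out 1 library gave 1 to 1338 genes, 0 to 376 higher and 1 to 962 lower, with the upper ends without WT replicate 1. Of those 1338 genes, 671 were also among the 831. The Egfr log2 fold change ranged from -1.53 to -1.34 on leaving out 1 library. It was -1.45 with limma-voom (adjusted p = 0.0534), -1.45 with the replicate block (0.0501) and -1.66 with the vessel wall covariate (0.351), past the threshold in none of these 3, and over all settings its adjusted p ranged from 6.58e-14 (DESeq2) to 0.353. Lists past the threshold numbered 0 with an estimated correlation, 0 with fry (smallest adjusted p 0.324) and 13 to 23 on leaving out 1 library, with 23 without KO replicate 2, and 14 with library totals only, 12 at a mean CPM of at least 5 and 14 with the vessel wall covariate. The cause was not tested. Replicate numbers are shared by WT and KO, and the design chosen beforehand did not use them as pairs in the main fit. The deviations from the group means of same-numbered pools correlated at 0.10, -0.16 and 0.01. WT replicate 2 correlated best with KO replicate 3 (0.15). The pools numbered 1 did share Y-linked expression. With the replicate block, 3 genes passed, 2 higher and 1 lower, with Igha among the higher (3.55, adjusted p = 0.0118), and 17 lists. These included 4 that had not passed: MAPK feedback (median -0.28, adjusted p = 0.0417) and platelet genes (-0.52, 0.0278) as lower, and adhesion and migration receptors (0.20, 0.0331) and NADPH oxidase genes (0.14, 0.021) as higher. With the block and bias-adjusted deviances, 106 passed (17 higher, 89 lower).

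A direction here is that of the list test, which can differ from the sign of the median. Immediate early and cell cycle lists turned from up to down at a mean CPM of at least 5 (medians -0.0268 and -0.16) and with fry (-0.0027 and -0.14), with negative medians throughout. On leaving out 1 library the medians ranged from -1.33 to 2.29 for T cells, -0.92 to 0.77 for neutrophils, -0.28 to 0.34 for the cell cycle, -0.44 to 0.0058 for NK cells, -0.32 to 0.0676 for mitochondrially encoded genes, 0.0025 to 0.52 for classical monocytes, -0.10 to 0.0511 for nonclassical monocytes, -0.0801 to 0.27 for NF-kB genes, -0.0451 to 0.13 for interferon genes, -0.0405 to 0.22 for matrix remodelling and -0.12 to 0.12 for immediate early genes. Without a turn they ranged from -0.18 to -0.12 for MAPK feedback, -0.22 to -0.13 for the EGFR family, 0.0094 to 0.42 for alternative activation, 0.0127 to 0.29 for NADPH oxidase, 0.0525 to 0.24 for cholesterol genes, 0.0623 to 0.43 for adhesion receptors, 0.0067 to 0.12 for oxidative phosphorylation, 0.0555 to 0.14 for apoptosis and 0.0132 to 0.12 for glycolysis. The vessel wall and fibroblast covariate, which removes much of the genotype difference by its construction, turned Itgam to -0.14, and 3 lists that had passed, with medians of 0.41 for fibroblast, 0.0903 for cardiomyocyte and -0.0233 for MHC class II genes. It also turned lists that had not passed, with medians of -0.68 for neutrophil genes, -0.11 for NF-kB genes, -0.13 for alternative activation, -0.24 for adhesion and migration receptors, -0.0851 for NADPH oxidase and antioxidant genes, -0.0143 for apoptosis and 0.0489 for glycolysis. At the depth of these libraries, 55 of 100 simulated 2-fold changes were recovered in KO against WT over 15707 genes, so changes of that size or smaller can be missed. Larger changes can be missed too, as Igha did not pass (log2 fold change 3.41, edgeR adjusted p = 0.148). Simulated genes varied independently of each other, so the simulation may overstate what the test recovers.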

Other observations

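Except for the counts of calls by DESeq2 and edgeR, the tests in this part were chosen after the result was seen. Most antibody genes had positive log2 fold changes, in a class defined after the named antibody genes, which it includes, were seen. Of 157 immunoglobulin genes tested, 144 had positive log2 fold changes, with a median of 1.25. In 82 of them every KO pool lay above every WT pool and in 0 every KO pool lay below. No p-value is given for the class, because it would restate the observation that led to it. DESeq2 called 58 of the 157 higher and 0 lower, and edgeR without its expression filter called 55 higher and 0 lower, while 0 passed in edgeR with the filter and all 6 libraries. In edgeR without WT replicate 1, 31 were higher and 1 lower. Short, similar segments share reads, so single segments are uncertain.

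Other lists, written after related genes had been seen, were summarised by their medians. The median log2 fold change of 15 plasma cell genes was 0.32, with Jchain at 1.76 and the surface marker Sdc1 at -0.41. For 13 genes of serous cavity macrophages it was 0.51, with Cd5l at 2.72, Alox15 at 2.55, Prg4 at 1.80 and Gata6 at -0.76, and the level in KO replicate 3 lay within the WT range. For 15 genes of the unfolded protein response it was 0.42, and 10 of them lay higher in every KO pool. Camera with an estimated correlation gave the unadjusted p-values 0.0569, 0.157 and 0.0803 for these lists in that order.

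Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as the 2 genes called between genotypes, and the highest of the others gave 0. Each other split mixed WT and KO pools on both sides, so the Lyz2 and Egfr differences fell within its groups. This count therefore cannot tell how often chance would call genes. For gene lists, 8 of the 10 splits gave at least the real 13, and the highest of the others gave 25. With 10 splits the share cannot fall below 0.1. The split with 25 lists joined WT replicate 1 with KO replicates 1 and 3, which is not a split by genotype. It set both libraries with Y-linked expression, WT replicate 1 and KO replicate 1, on the same side, while the real split has 1 in each group. Splits that joined these libraries gave 17 to 25 lists. The other splits apart from the real one gave 8 to 19.

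Lower vessel wall and fibroblast markers in KO had a median log2 fold change of -1.00 over 55 genes. A smaller share of every non-myeloid cell type in the KO pools would lower B cell markers too, but their median was 0.631 (lower quartile 0.51). That list includes the antibody genes Igkc, Ighd and Ighm. Cardiomyocyte (-0.50), mesothelial (-0.68), Schwann (-0.76) and erythroid (-3.77, or -1.01 without WT replicate 1) medians were negative. A smaller share of non-myeloid cells other than B cells was therefore not excluded. T and NK cell medians were negative, though each depended on 1 library. The T cell median was 2.29 without WT replicate 2, and the NK cell median was 0.0058 without KO replicate 1. Removing a trend on transcript length and GC content left the median at -0.872 (upper quartile -0.64), which argues against such a bias as the whole cause. Uneven carry-over of these cells between pools, whatever the genotype, cannot be told apart from a genotype effect, since Cd11b beads should remove them and yet Col3a1 was at 954 ± 545 CPM in WT and 379 ± 88.7 CPM in KO. The WT pools differed among themselves by 1.00 (log2 CPM) in mean marker level, the KO pools by 0.176, the groups by -0.88 (exact permutation p = 0.1, the smallest possible), and both stay open.

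Near loss of Lyz2 with higher Lyz1 would, with fewer macrophages as the cause, go with lower levels of their other markers, but the resident macrophage median was 0.526. If all lost Lyz2 reads had been assigned to Lyz1, their sum would stay level, but it was lower by a log2 difference of -2.36 (SE 0.27). The sum cannot show whether a smaller part of the Lyz2 reads was assigned to Lyz1. Reads aligned to several places were not counted for either gene. A widely used myeloid deletion strain carries the Cre recombinase gene inside Lyz2, and the labels do not name the driver. Whether such a driver was used here was not tested, because the tables hold 1 count per gene, and neither the loss of Lyz2 nor the higher Lyz1 was explained. Lyz2 and Egfr fell in the same KO pools, so other differences between the groups cannot be assigned to Egfr alone.

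Egfr was lower in the same libraries that had lower vessel wall and fibroblast markers, and fibroblasts also express it. With the mean marker level as a covariate its log2 fold change was -1.66 (SE 0.22, against -1.46 and SE 0.13 without). Single markers were lower by about as much as Egfr, as with Abcc9 (-1.44, SE 0.23) and Kdr (-1.36, SE 0.24). The edgeR adjusted p was 0.351 with the covariate, where the fit had fewer residual degrees of freedom and a larger SE, so the call ended. The mean marker level did not overlap between the groups (log2 CPM 6.986 to 7.99 in WT, 6.489 to 6.665 in KO). Genotype and covariate are therefore hard to separate. WT replicate 1, the lowest WT pool in marker level, was the highest in Egfr (54.7 CPM). Carry-over of those cells may contribute to the Egfr level, and this fit cannot tell whether it is the whole cause. Deletion in myeloid cells is given by the labels, and its share of the lower Egfr level was not measured.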
